A study of Mus musculus with 12 samples.

How the data were processed

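Colon tissue of mice was profiled by RNA sequencing in 12 libraries, 3 in each of the groups Ctrl, ImP, DSS and DSS_ImP, as the labels give them. Per the labels, total RNA was extracted with Trizol, messenger RNA was captured with oligo(dT), and libraries marked the strand with dUTP. Whether counting used the strand is not given in the sources used here. The estimated counts were deposited by the authors as whole numbers per gene, without scaling for library size. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used upstream. The FPKM values were deposited by the authors beside the counts and are, per the file headers, fragments per kilobase of transcript scaled to the library. In 561 values under 60 counts from genes with a single transcript, 100% of counts exceeded the number that the FPKM implies by 0 to 1 (tolerance 0.05), so the counts were taken as estimates rounded up. Counts of 4 were in excess (12215 cells, against 7060 with 3 and 4182 with 5), so 1 read pair was taken to add about 4 counts, and the floor for a group with 0 counts was set at 12 counts over the group. Floors cover counting error only. The processing notes name the build GRCm38, but only 663 of 33695 shared gene identifiers have the coordinates of GENCODE M21, so no positions are given.

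The table held 35841 genes, of which 1627 had 0 counts in all libraries. Total counts per library ran from 55419380 to 67406087, at which the floor corresponds to between 0.0570 and 0.0707 CPM by group. Genes were filtered with filterByExpr by group, which left 22279, normalised by the trimmed mean of M-values (TMM; factors 0.921 to 1.12) and tested in R 4.3.3 with edgeR 4.0.16 in its quasi-likelihood fit over all 12 libraries with 1 coefficient per group. The common biological coefficient of variation was 0.312. Genes were called at an FDR of 0.05 by Benjamini-Hochberg adjustment over the tested genes, and tests were two-sided. Standard errors of log2 changes were computed as the absolute log2 change over the square root of F. The comparisons were DSS with Ctrl, DSS_ImP with DSS, ImP with Ctrl, DSS_ImP with ImP, and the interaction, the DSS change with ImP minus that without it. Mean CPM used TMM-normalised library sizes, and the summed liver and pancreatic traces used library totals. Gene lists, 36 with 700 members of which 695 matched the table, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over the 36 lists. A list's counts are also given adjusted over the list alone.

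The comparisons, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. Named genes were, in each direction of a comparison, the 10 with the largest log2 change among called genes with a symbol, with all 3 libraries of one group above or below all 3 of the other, and with at least 1 FPKM on average in the higher group. Predicted genes were left out, and 75.7% of tested genes met the symbol rule. For the interaction the 10 genes with the smallest p were taken, and for each list up to 4 members with the smallest p. The batches were defined after the data were seen, by a liver trace of at least 50 CPM or a pancreatic trace of at least 5 CPM. Batch as a term was fitted for DSS with Ctrl and ImP with Ctrl, and the batch effect rests on the DSS libraries, the only group found in both batches A and B. For a group with 1 library in a batch, the fit assumes that it varies like the other groups.

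The tests were tried on simulated negative binomial counts with the means, library sizes and dispersions of the measured table and known changes. In the 4 comparisons of 3 against 3 libraries, between 56.6% and 69.8% of genes changed 4-fold and between 40.0% and 46.9% of genes changed 2-fold were recovered, and between 2.68% and 5.61% of calls were false. In the interaction the values were 54.0%, 23.7% and 6.10%. A list shifted by 1 on the log2 scale was recovered in each of the 5 comparisons. Of the 35 other lists, 1 was called in the interaction and 0 in each pairwise comparison. Genes were drawn independently of each other, so this does not test camera where genes of a list are correlated. Spearman correlations between replicates were 0.975 to 0.983, and the spread between replicates was 10.2 to 34.2 times what counting alone would give (chi-square per degree of freedom, on counts divided by 4). Alternatives tried were DESeq2 1.42.0 size factors and Wald test, limma on log2 FPKM with a pseudocount of 1, no filter, a filter of 1 CPM in at least 6 libraries, the replicate number as a block, only the groups compared, counts divided by 4, batch as a term, and each library left out in turn. The FPKM fit kept genes with at least 1 FPKM in at least 3 libraries. Its list medians therefore cover only the members that passed this filter, and the pseudocount shrinks changes of low genes. Alignment of reads was not part of this work, and transcripts, splicing and sequence variants were not analysed here. Some genes that the rule names are not reported here.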

Results

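RNA sequencing of mouse colon tissue gave 12 libraries in 4 groups of 3. The groups were Ctrl, ImP, DSS and DSS_ImP, the last of which received both agents. DSS, dextran sulfate sodium, is a sulfated polymer that injures the colon epithelium and is widely used to induce colitis in mice. The labels do not spell out ImP. The series text describes colitis, with ImP given or not given over 7 days, and its title names Angelica dahurica polysaccharides, which the library labels do not mention. The libraries held between 55419380 and 67406087 estimated counts each. Values below are mean counts scaled to a common library size (CPM) ± SD over n = 3 libraries, and log2 changes ± SE. A gene is said to have risen or fallen only where it passed edgeR's quasi-likelihood test at a false discovery rate (FDR) of 0.05 over the 22279 genes tested. The labels do not say whether the libraries come from separate animals, so the p-values measure only the spread between these samples. For each gene named for the size of its change, all 3 libraries of one group lay above all 3 of the other.

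Transcripts of other organs split the libraries across the groups. Liver transcripts summed to between 141 and 182 CPM in the 3 Ctrl libraries and in DSS 2, with albumin (Alb) at 36.1 to 45.8 CPM, and to no more than 3.36 CPM in the other 8 libraries. Pancreatic enzyme transcripts summed to between 13.3 and 17.3 CPM in DSS 3, DSS 5 and the 3 ImP libraries, and to 4.38 CPM in Ctrl 4. The DSS_ImP libraries carried neither trace. These sets of libraries, found in the data and not given by the labels, are called batches A (Ctrl 1, 4 and 5 and DSS 2), B (DSS 3 and 5 and the ImP libraries) and C (the DSS_ImP libraries). DSS and Ctrl can be compared within batch A with 1 DSS library, and ImP and DSS within batch B. No batch holds DSS_ImP with another group, so for every comparison with DSS_ImP the batch and the group cannot be told apart. Mitochondrial transcripts made up 6.38% to 7.55% of counts in Ctrl, 6.0% to 6.34% in DSS, 5.40% to 6.01% in ImP and 4.67% to 5.14% in DSS_ImP, so their share also moves with the groups.

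**Figure D1:**
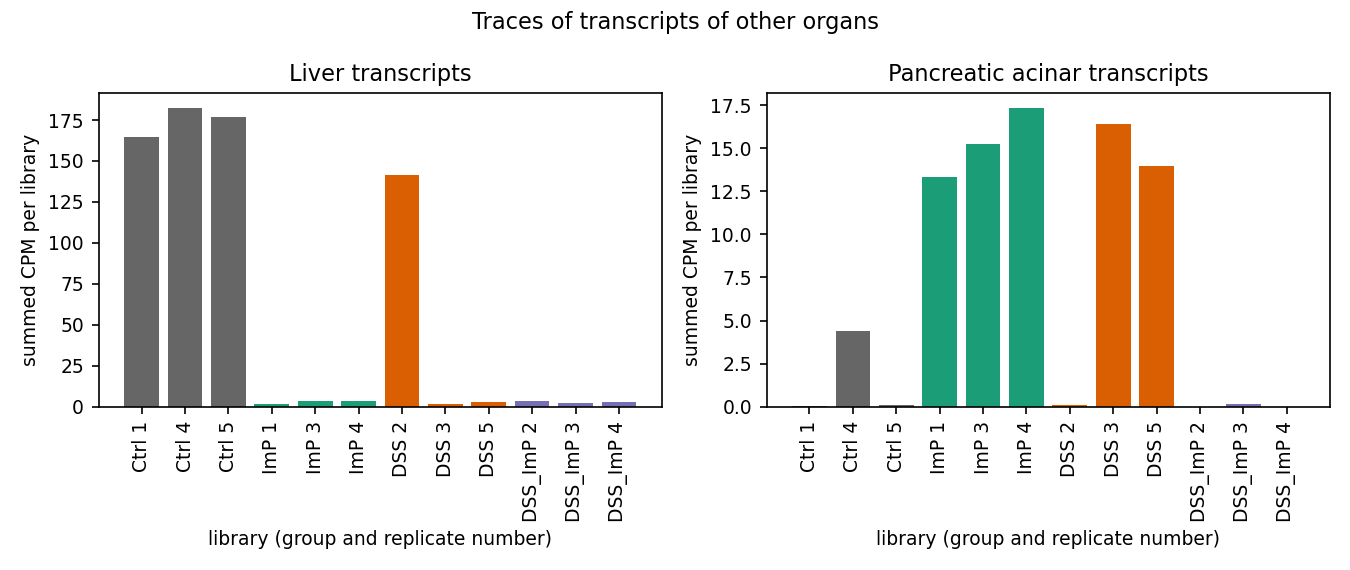
Summed CPM of liver transcripts and of pancreatic enzyme transcripts in each of the 12 libraries, with 1 bar per library. The liver bars reach 141 to 182 CPM in Ctrl 1, 4 and 5 and in DSS 2, and the pancreatic bars 13.3 to 17.3 CPM in DSS 3, DSS 5 and the ImP libraries.

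DSS was compared with Ctrl to ask what DSS changed in colon that had not received ImP. Interferon-response genes fell together: 23 of the 26 measured members fell and 0 rose, and the median log2 change of the list was -1.99. Ifi44 (ENSMUSG00000028037), an interferon-induced gene, fell from 76.5 ± 17.9 to 6.92 ± 3.39 CPM, and Isg15 (ENSMUSG00000035692), a ubiquitin-like protein made in response to interferon, fell from 96.1 ± 12.1 to 10.5 ± 2.98 CPM. S100a9 (ENSMUSG00000056071), a subunit of the neutrophil protein calprotectin, rose from 0.0962 ± 0.0855 to 10 ± 5.40 CPM. Mmp10 (ENSMUSG00000047562), a matrix-degrading protease, rose from 0.322 ± 0.133 to 10.3 ± 4.26 CPM.

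Members of several inflammatory and epithelial groups rose in DSS. Of the 17 neutrophil markers measured, 4 rose and 0 fell (12 up and 0 down when adjusted over the list alone). Their median log2 change was 2.35, or 1.65 with genes that had 0 counts in a group held at their bound. The risers were S100a9 (log2 change 6.70 ± 0.98) and S100a8, its partner in calprotectin (6.41 ± 1.59 CPM in DSS and 0.0595 ± 0.103 CPM in Ctrl). They also included Ly6g, a granulocyte surface marker (4.33 ± 0.83), and Mmp9, a gelatinase stored in neutrophil granules (2.42 ± 0.45). Ly6g rose in ImP against Ctrl too (5.17 ± 0.86), where the median of this list was 0.48, so Ly6g did not move with the list there. Among 28 inflammatory cytokines and chemokines, 4 rose and 2 fell (11 up and 2 down when adjusted over the list alone). The median was 1.39, or 1.20 at the bounds. The neutrophil chemokines Cxcl5 and Cxcl2 rose by 5.23 ± 0.86 and 3.6 ± 0.67 on the log2 scale, Il11, a cytokine of the interleukin-6 family, by 3.40 ± 0.55 and Il1b by 1.85 ± 0.43 (1.21 without DSS 3). The chemokines induced by interferon gamma, Cxcl9 and Cxcl10, fell (log2 changes -2.02 ± 0.43 and -1.80 ± 0.41). Of 20 genes of epithelial antimicrobial defence, 6 rose and 1 fell (14 up and 2 down when adjusted over the list alone; median 1.60). Rises included Lcn2, which binds bacterial siderophores (2.84 ± 0.46), Retnlb, a goblet cell antibacterial protein (2.17 ± 0.42), Il18 (2.46 ± 0.33) and Duoxa2, the maturation factor of the epithelial oxidase DUOX2 (2.02 ± 0.43). The defensin Defb37 fell (-2.44 ± 0.54). Of 25 extracellular matrix genes, 5 rose (11 up and 0 down when adjusted over the list alone; median 0.64). The risers were the proteases Mmp10 (4.99 ± 0.66) and Mmp3 (3.75 ± 0.70), the collagen cross-linking enzyme Lox (1.68 ± 0.30), Timp1 (2.49 ± 0.48) and Mmp14 (0.64 ± 0.14). These 4 lists passed camera, a test of a list against all other genes. With an estimated correlation their adjusted p was 0.121 for neutrophil markers, 0.157 for cytokines and chemokines, 0.0767 for antimicrobial defence and 0.172 for extracellular matrix. In limma on log2 FPKM the medians were 0.41 for neutrophil markers and 0.49 for cytokines, and in the lists below -0.36 for fat oxidation, -0.15 for enteroendocrine and -0.37 for tuft cell markers. Genes of interferon response, detoxification and fat oxidation were among those that fell in DSS. In the interferon list 0 rises and 26 falls were called when adjusted over the list alone. Examples were the RNA-sensing synthetase Oas1a (log2 change -1.59 ± 0.18), Oasl2 (-2.49 ± 0.29), the transcription factor Irf7 (-1.99 ± 0.25) and the nucleic acid sensor Zbp1 (-1.35 ± 0.16). Of 29 xenobiotic metabolism genes, 9 fell and 0 rose (0 up and 18 down when adjusted over the list alone; median -0.66). Examples were the drug efflux pump Abcb1a (-1.70 ± 0.19), the carboxylesterase Ces1f (-1.72 ± 0.20) and the cytochrome P450 Cyp2c55 (-1.81 ± 0.27). Of 27 genes of fatty acid oxidation and PPAR targets, 5 fell (0 up and 15 down when adjusted over the list alone; median -0.57). They were the intestinal fatty acid binding protein Fabp2 (-2.10 ± 0.32), the carnitine palmitoyltransferase Cpt1a (-0.58 ± 0.11), Ehhadh (-0.83 ± 0.10), Hadh (-0.62 ± 0.13) and Acadvl (-0.57 ± 0.12). With an estimated correlation the adjusted p was 0.0331 for interferon response and 0.0331 for xenobiotic metabolism, which both kept their call, and 0.0767 for fat oxidation, which did not. The hormone-cell genes Chga (-1.18 ± 0.18), Chgb (-0.93 ± 0.17), Tph1 (-0.91 ± 0.19) and Sct (-1.37 ± 0.31) also fell. They were 4 of 15 enteroendocrine markers (0 up and 4 down when adjusted over the list alone; median -0.36), with an adjusted p of 0.172 for the list with an estimated correlation. Camera also called lower MHC class II genes (median -0.80) and T and NK cell markers (-0.50), with an adjusted p of 0.322 and 0.481 with an estimated correlation. In edgeR 0 of 10 and 0 of 20 members passed over all genes, with 0 up and 7 down, and 0 up and 4 down, when adjusted over the list alone. Other cell-type lists that camera called were smooth muscle markers (median 0.36, or 0.56 without Ctrl 1), enteric neuron and glia markers (0.33, or -0.066 without DSS 2, where the call was lost) and tuft cell markers (-0.67). Their adjusted p was 0.61, 0.644 and 0.322 with an estimated correlation, and within batch A their medians were 0.51, 1.08 and -0.43. Absorptive colonocyte genes moved both ways, with 4 up and 3 down of 26 (5 up and 9 down when adjusted over the list alone). The list did not pass (median -0.09, camera adjusted p 0.404). The water channel Aqp4 (2.40 ± 0.35), the sodium/hydrogen exchanger Slc9a3 (1.32 ± 0.27), Hsd11b2 (1.07 ± 0.15) and Slc26a3 (1.12 ± 0.26) rose. Cyp2c55, the carbonic anhydrase Car1 (-1.77 ± 0.31) and Guca2a (-0.92 ± 0.17) fell. Among the members named here, Cxcl10, Defb37, Mmp14, Acadvl, Slc9a3, Slc26a3 and Guca2a were chosen after their values were seen. With 1 library left out, members lost their call in edgeR, and brackets give the highest adjusted p and the libraries: Ly6g (0.0849, Ctrl 1 or 4), Mmp9 (0.0741, Ctrl 1 or 4), S100a8 (0.0925, Ctrl 1, 4 or 5) and Cxcl2 (0.0735, Ctrl 4 or 5). Il1b (0.143, Ctrl 1, 4 or 5 or DSS 2 or 3 or ImP 1 or 3), Cxcl9 (0.0857, Ctrl 1, 4 or 5 or DSS 5), Retnlb (0.0822, Ctrl 1, 4 or 5 or DSS 2 or 5) and Duoxa2 (0.0998, Ctrl 1, 4 or 5 or DSS 2, 3 or 5) did so too in edgeR. Mmp3 (0.0734, Ctrl 1 or 5), Lox (0.0579, Ctrl 4), Timp1 (0.0682, Ctrl 4 or 5 or DSS 3) and Cpt1a (0.0622, Ctrl 4 or DSS 2) did so too in edgeR. Hadh (0.0847, Ctrl 1, 4 or 5 or DSS 2 or 3), Chgb (0.0707, Ctrl 1 or 4 or DSS 2 or 5) and Tph1 (0.0991, Ctrl 1 or 4 or DSS 2 or 5) did so too in edgeR. Sct (0.131, Ctrl 1 or 4 or DSS 2, 3 or 5) and Car1 (0.0566, DSS 5) did so too in edgeR.

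In all, 269 genes rose and 354 fell in DSS against Ctrl, 623 in total. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00331 for Ifi44, 0.00353 for Isg15, 0.00467 for S100a9, 0.00296 for Mmp10 and 0.0149 for Clca4b. Other genes with large rises were Clca4b, of the calcium-activated chloride channel regulator family (from 21 ± 5.28 to 1151 ± 80.2 CPM), and Prss22, a serine protease with 0 counts in Ctrl (at least 46.4-fold higher in DSS, against a floor of 12 counts over the Ctrl group). Scnn1g, the gamma subunit of the epithelial sodium channel (4.43 ± 2.10 against 0.0227 ± 0.0394 CPM), Gml (2.45 ± 0.391 against 0.0182 ± 0.0315 CPM), Sprr2h (2.51 ± 1.44 against 0.0364 ± 0.0630 CPM) and Nt5c1a (2.15 ± 1.12 against 0.0654 ± 0.113 CPM) rose as well. The other large falls were in Oas2 (log2 change -2.80 ± 0.37), Apol9b (-3.30 ± 0.51), Apol9a (-2.88 ± 0.43), BC023105 (-3.20 ± 0.67), Slc16a9 (-2.93 ± 0.38), Pla2g4c (-2.83 ± 0.66), Ces1g (-2.76 ± 0.26) and Cyp4b1 (-2.74 ± 0.36). Within batch A, where 1 DSS library stood against 3 Ctrl libraries and was assumed to vary like the others, 52 genes passed (27 up, 25 down), 46 of them among the 623. The batch A median was -2.03 for interferon response, 2.37 for neutrophil markers, 0.85 for cytokines, 1.59 for antimicrobial defence, 0.19 for extracellular matrix, -0.54 for xenobiotic metabolism, -0.53 for fat oxidation, -0.71 for MHC class II and -0.43 for T and NK cell markers. Within batch A, edgeR's adjusted p stayed under the threshold for S100a9 (0.0425), Mmp10 (0.0207), Oas2 (0.0326) and Ces1g (0.0164), and not for Clca4b (0.0857), Ifi44 (0.0773) or Isg15 (0.0909). The log2 changes of those 3 were 5.78 ± 1.08, -3.47 ± 0.47 and -3.19 ± 0.44 before and 5.79 ± 1.23, -3.90 ± 0.79 and -3.38 ± 0.74 within batch A, so the SE grew and the changes did not shrink. The count of 623 was 1457 with DESeq2. It was 268 without Ctrl 4, 285 without DSS 5, 332 without Ctrl 1, 368 without DSS 3, 374 without DSS 2 and 409 without Ctrl 5. Among the genes of this paragraph, calls were lost in edgeR when 1 library was left out, with the highest adjusted p and the libraries in brackets, for Clca4b (0.0724, Ctrl 1, 4 or 5), Nt5c1a (0.0653, Ctrl 4 or 5), BC023105 (0.0936, Ctrl 1, 4 or 5 or DSS 2, 3 or 5) and Pla2g4c (0.141, Ctrl 4 or 5 or DSS_ImP 2 or DSS 2, 3 or 5 or ImP 3).

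**Figure D2:**
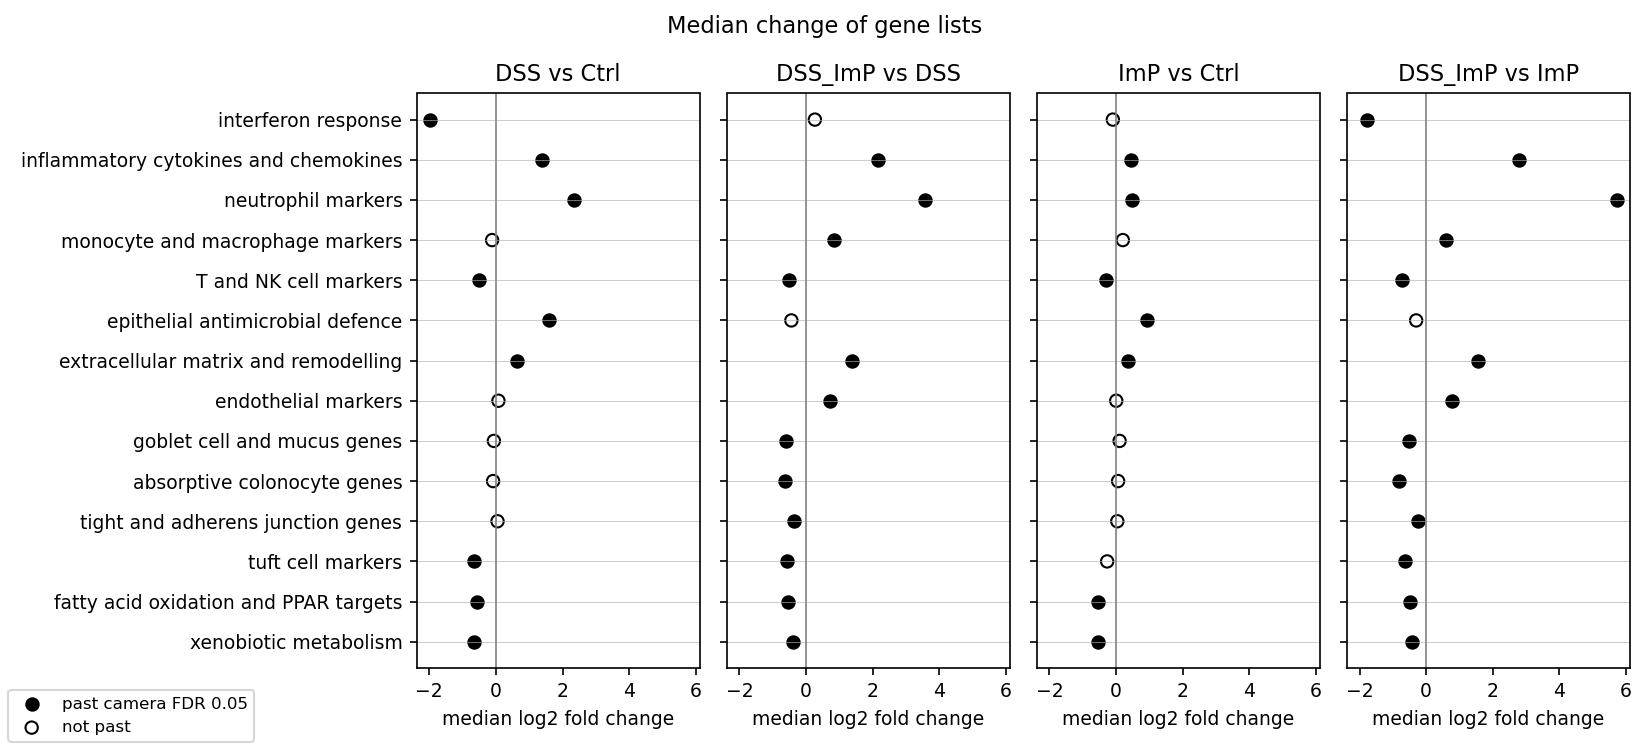
Median log2 change of 14 gene lists in the 4 pairwise comparisons, with 1 point per list and comparison and filled points for lists past a camera FDR of 0.05. The interferon median is -1.99 in DSS against Ctrl and -0.10 in ImP against Ctrl, and the neutrophil median is 3.56 in DSS_ImP against DSS.

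DSS_ImP was compared with DSS to ask what ImP changed in colitis, the comparison that the series text names. Members of the neutrophil, cytokine and matrix lists were higher in DSS_ImP and members of the absorptive colonocyte list lower. These list changes passed camera, but 0 held with an estimated correlation. Ngp (ENSMUSG00000032484), a neutrophil granule protein, rose from 0.222 ± 0.105 to 45.0 ± 38.9 CPM, and Csf3 (ENSMUSG00000038067), the granulocyte colony-stimulating factor, rose from 0.237 ± 0.107 to 10.9 ± 5.76 CPM. Il1b (ENSMUSG00000027398), a central inflammatory cytokine, rose from 13.8 ± 9.18 to 139.9 ± 63.2 CPM. Slc13a1 (ENSMUSG00000029700), an epithelial sulfate transporter, fell from 50.1 ± 7.17 to 11.8 ± 7.42 CPM.

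Of 17 neutrophil markers, 12 rose and 0 fell (16 up and 0 down when adjusted over the list alone; median 3.56). Examples were S100a9 (log2 change 4.56 ± 0.67), Retnlg (4.62 ± 0.71) and Fpr1, a receptor for bacterial formyl peptides (3.36 ± 0.53). Of 28 cytokines and chemokines, 18 rose and 0 fell (19 up and 0 down when adjusted over the list alone; median 2.17). Among them were the chemokines Cxcl3 (4.98 ± 0.61), Cxcl2 (4.37 ± 0.59) and Ccl2 (2.15 ± 0.27). Of 25 matrix genes, 23 rose and 0 fell (25 up and 0 down when adjusted over the list alone; median 1.39). Examples were thrombospondin Thbs1 (2.60 ± 0.31) and fibronectin Fn1 (1.44 ± 0.22). Of 20 monocyte and macrophage markers, 13 rose and 0 fell (16 up and 0 down when adjusted over the list alone; median 0.83). They included Itgam (2.02 ± 0.27), the scavenger receptor Cd163 (2.39 ± 0.38) and Chil3 (4.48 ± 0.77). With an estimated correlation the adjusted p was 0.0608 for neutrophil markers, 0.0608 for cytokines, 0.0608 for matrix and 0.0994 for macrophage markers. None of these camera calls held there. T and NK cell markers had a median of -0.51, with Cd3e (-0.87 ± 0.20) and Cd8a (-0.85 ± 0.18) falling and 0 of 20 rising. That camera call had an adjusted p of 0.675 with an estimated correlation, and it was lost without DSS_ImP 4, where the median was -0.39, while without DSS 2 the median was -0.33. Camera also called endothelial markers (median 0.71, or 0.43 without DSS_ImP 3), enteric neuron and glia markers (0.75, or 1.23 without DSS 2) and B and plasma cell markers (1.29). It called cell cycle genes (0.67, with 0.42 without DSS 2 and 1.12 without DSS 3) and smooth muscle markers (0.23, or 0.10 to 0.34 with 1 library left out, a call lost without DSS_ImP 2 or DSS 3). The adjusted p of these 5 lists with an estimated correlation was 0.39, 0.448, 0.448, 0.448 and 0.687. Of 26 absorptive colonocyte genes, 14 fell and 0 rose (1 up and 17 down when adjusted over the list alone; median -0.64). The falls included the brush border cadherins Cdhr5 (-0.70 ± 0.10) and Cdhr2 (-0.69 ± 0.12) and the sodium/hydrogen exchanger Slc9a2 (-0.92 ± 0.15). Of 19 goblet cell and mucus genes, 4 fell (0 up and 9 down when adjusted over the list alone; median -0.59). They were Atoh1, the transcription factor of secretory cell fate (-0.89 ± 0.19), Klk1 (-0.93 ± 0.14), Galnt12 (-0.62 ± 0.14) and B3gnt6 (-0.91 ± 0.21). Of 21 junction genes, 9 fell and 1 rose (2 up and 12 down when adjusted over the list alone; median -0.36). Cldn23 (-0.83 ± 0.14) and Tjp3 (-0.56 ± 0.12) fell, and the riser was claudin 1, Cldn1 (2.62 ± 0.47). Fat oxidation genes had 13 falls and 1 rise of 27 (1 up and 21 down when adjusted over the list alone; median -0.53). The nuclear receptor Ppara (-1.41 ± 0.26) was among the falls, and Angptl4 was the rise (1.74 ± 0.38). Xenobiotic metabolism genes had 10 falls and 2 rises of 29 (2 up and 11 down when adjusted over the list alone; median -0.40). Ces1f (-1.40 ± 0.20) was among the falls, and heme oxygenase Hmox1 (1.52 ± 0.24) and Tiparp (0.53 ± 0.11) were the rises. With an estimated correlation the adjusted p was 0.0608 for absorptive, 0.0851 for goblet, 0.0918 for junction, 0.0889 for fat oxidation and 0.0608 for xenobiotic genes. In limma on log2 FPKM the medians were 2.31 for neutrophil, -0.36 for goblet and -0.33 for T and NK cell genes. The tuft cell genes Trpm5, a cation channel of taste signalling (-1.59 ± 0.21), Sh2d6 (-1.45 ± 0.24), Sh2d7 (-1.77 ± 0.29), Avil (-0.65 ± 0.18) and Il25, which had 0 counts in DSS_ImP, fell, and Ptgs1 rose (0.47 ± 0.12). They made 5 falls and 1 rise of 14 tuft markers (1 up and 6 down when adjusted over the list alone; median -0.58). That list had an adjusted p of 0.448 with an estimated correlation and a median of 0.095 in limma on FPKM, -0.34 without DSS_ImP 3 and -0.36 without DSS 2. Interferon-response genes did not pass as a list (median 0.27, camera adjusted p 0.115). Gbp5, an interferon-induced GTPase, was the 1 member of 26 that rose (1.16 ± 0.31). Antimicrobial genes did not pass either (median -0.44, camera adjusted p 0.633). Within them Lcn2 (3.58 ± 0.44), the protease inhibitor Slpi (3.33 ± 0.67) and Saa3 (2.96 ± 0.61) rose and Pigr, which carries IgA across the epithelium, fell (-0.66 ± 0.17). Angptl4, Hmox1, Tiparp, Avil and Ptgs1 were chosen after their values were seen. Leaving out 1 library ended the call in edgeR, with the highest adjusted p and the libraries in brackets, for Cd3e (0.0913, DSS_ImP 2 or 3 or DSS 2, 3 or 5), Cd8a (0.0617, DSS_ImP 2 or 3 or DSS 2), Atoh1 (0.0643, DSS_ImP 3 or DSS 2) and Galnt12 (0.0857, DSS_ImP 2 or 3 or DSS 5). B3gnt6 (0.0811, DSS_ImP 2 or DSS 2 or 5), Il25 (0.0866, DSS_ImP 2 or 3 or DSS 2 or 5), Tjp3 (0.0789, DSS_ImP 2 or 3 or DSS 5) and Gbp5 (0.173, Ctrl 4 or DSS_ImP 2 or 3 or DSS 2 or 5) did so too in edgeR. Slpi (0.0626, DSS_ImP 3 or DSS 2 or 5), Saa3 (0.065, DSS_ImP 3 or DSS 2 or 5) and Pigr (0.133, DSS_ImP 2 or 3 or DSS 2 or 5) did so too in edgeR.

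In all, 888 genes rose and 901 fell in DSS_ImP against DSS, 1789 in total. In limma on log2 FPKM, which moves the median of all genes by 0.097 here and by 0.12 in DSS_ImP against ImP, 67.4% of calls were rises, against 49.6% in edgeR. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00419 for Ngp, 0.00494 for Csf3, 0.00419 for Il1b and 0.00972 for Slc13a1. Other large rises were in Mmp8, a neutrophil collagenase (log2 change 5.29 ± 0.96), Mrgpra2b (5.15 ± 0.86), Cstdc4 (5.85 ± 1.29) and Hoxd13 (5.76 ± 1.61). Hoxd13 varied widely between libraries. It stood at 12.3, 29.1 and 0.984 CPM in DSS_ImP 2, 3 and 4, and at 48.9, 0.536 and 2.46 CPM in ImP 1, 3 and 4. Stfa2 stood at 2.70 ± 2.98 against 0.0204 ± 0.0354 CPM, Serpinb2 at 2.70 ± 1.67 against 0.0204 ± 0.0354 CPM and Cstdc5 at 1.84 ± 1.95 against 0.0256 ± 0.0443 CPM. The immunoglobulin segment Ighv1-21 was at least 10.3-fold higher than its floor in DSS. The other large falls were in Ugt2b36 (-2.65 ± 0.30), Osr2 (-2.44 ± 0.44), Slc30a10 (-2.29 ± 0.34), Myrfl (-2.23 ± 0.58), Reg1 (-2.13 ± 0.57), Abca12 (-2.07 ± 0.46), Prap1 (-2.07 ± 0.46) and the deiodinase Dio1 (-2.05 ± 0.31). The pancreatic protease Ctrb1, a trace gene of batch B, was at least 60.0-fold lower. DSS_ImP has a batch of its own. Against the DSS libraries of batch B and of batch A separately, the medians were 3.96 and 3.61 for neutrophil markers, 2.19 and 2.54 for cytokines, 1.13 and 1.83 for matrix and -0.58 and -0.66 for absorptive genes. Other lists gave 0.63 and 1.44 for macrophage markers, 0.42 and 1.61 for cell cycle genes, 1.23 and 0.29 for enteric nerve, 0.34 and 0.08 for smooth muscle, -0.36 and -0.92 for tuft cell and -0.33 and -0.57 for T and NK cell markers. Against DSS 3 and 5 of batch B 775 genes passed. The batch A medians rest on 1 DSS library, DSS 2, so no count of genes is given against it. The count of 1789 was 3188 with DESeq2, 721 with only these groups fitted, 491 without DSS_ImP 3, 522 without DSS 5, 758 without DSS 2 and 820 without DSS_ImP 2. Among the genes of this paragraph, calls were lost in edgeR when 1 library was left out, with the highest adjusted p and the libraries in brackets, for Mmp8 (0.0641, DSS_ImP 3 or DSS 5), Mrgpra2b (0.0646, DSS_ImP 3 or DSS 2 or 5), Cstdc4 (0.105, DSS_ImP 2 or 3 or DSS 2) and Hoxd13 (0.156, Ctrl 1, 4 or 5 or DSS_ImP 2 or 3 or DSS 2, 3 or 5). Stfa2 (0.135, DSS_ImP 2 or 3 or DSS 2, 3 or 5), Serpinb2 (0.0577, DSS_ImP 3), Cstdc5 (0.204, DSS_ImP 2 or 3 or DSS 2, 3 or 5) and Ighv1-21 (0.0556, DSS_ImP 2 or DSS 5) did so too in edgeR. Myrfl (0.154, Ctrl 5 or DSS_ImP 2 or 3 or DSS 2 or 5), Reg1 (0.159, Ctrl 5 or DSS_ImP 2 or 3 or DSS 3 or 5 or ImP 1 or 3) and Abca12 (0.0771, DSS_ImP 2 or DSS 2 or 5) did so too in edgeR. Prap1 (0.0774, DSS_ImP 2 or 3 or DSS 3 or 5) and Ctrb1 (0.134, DSS_ImP 2, 3 or 4 or DSS 3 or 5 or ImP 1, 3 or 4) did so too in edgeR.

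**Figure D3:**
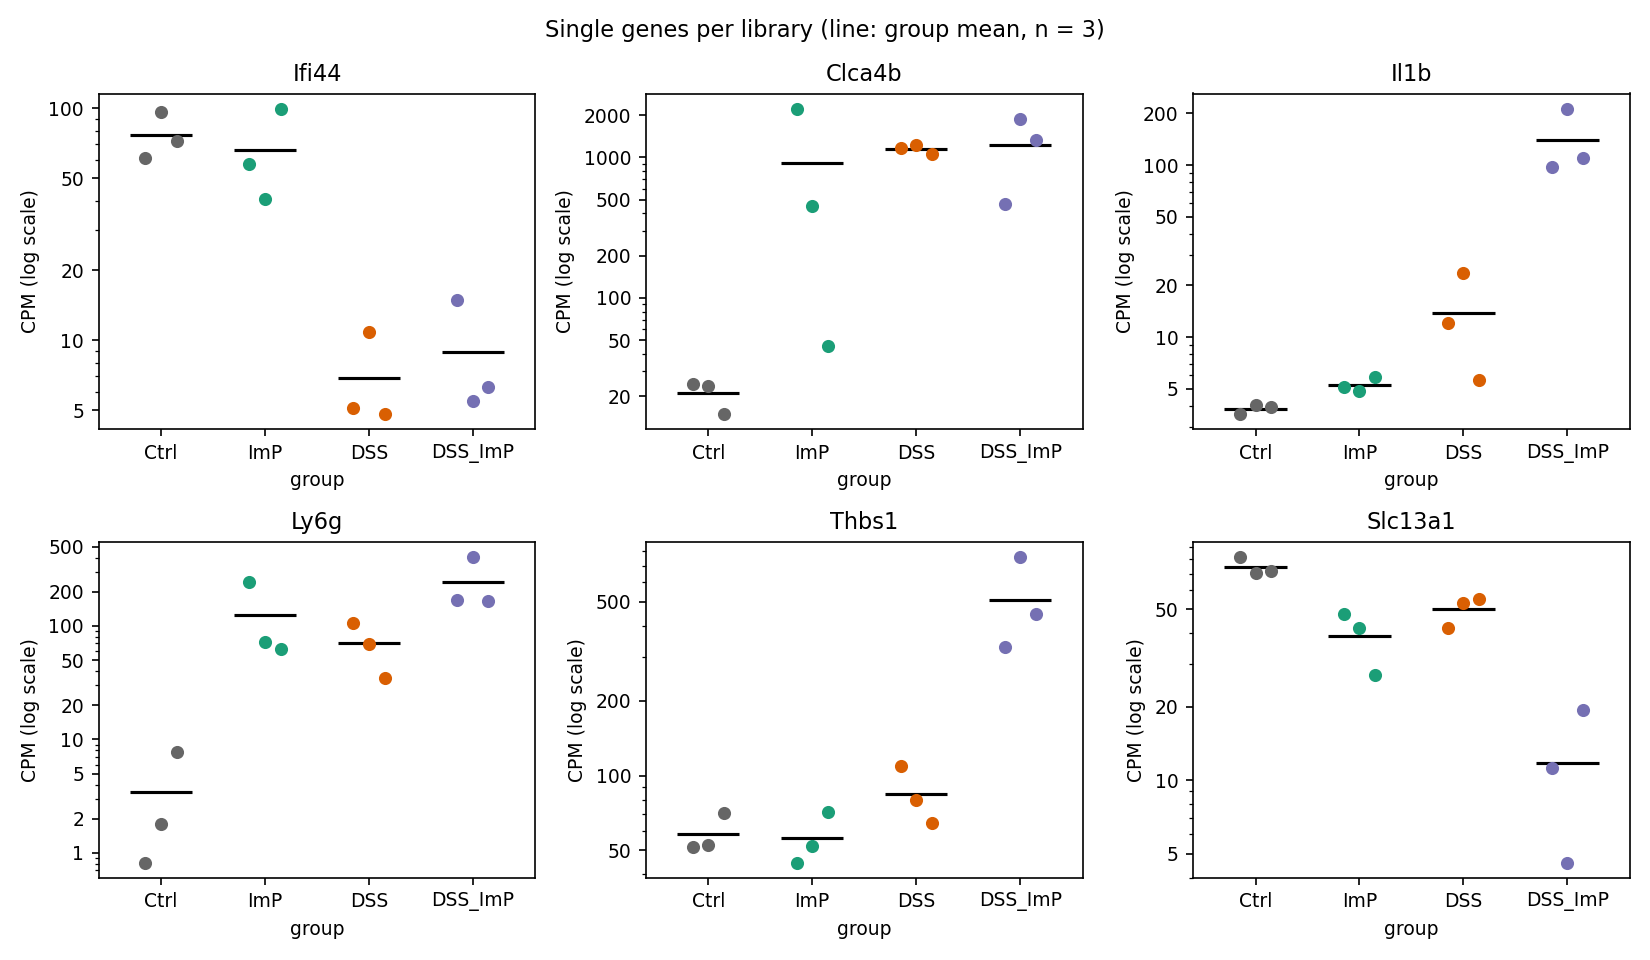
CPM on a log axis of Ifi44, Clca4b, Il1b, Ly6g, Thbs1 and Slc13a1 in the 12 libraries, with 1 point per library and a line at each group mean. Il1b averages 139.9 ± 63.2 CPM in DSS_ImP and 13.8 ± 9.18 CPM in DSS, and Ifi44 6.92 ± 3.39 CPM in DSS and 76.5 ± 17.9 CPM in Ctrl.

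ImP was compared with Ctrl to ask what ImP changed without colitis. Pla2g4f (ENSMUSG00000046971), a cytosolic phospholipase, rose from 1.38 ± 0.531 to 23.8 ± 16.1 CPM, and Aqp4 (ENSMUSG00000024411), a water channel, rose from 98.1 ± 54.1 to 664 ± 221 CPM. Sis (ENSMUSG00000027790), the brush border enzyme sucrase-isomaltase, fell from 17.0 ± 2.10 to 2.73 ± 0.869 CPM, and Cyp4b1 (ENSMUSG00000028713), a cytochrome P450, fell from 50.4 ± 4.44 to 8.96 ± 3.59 CPM. The whole ImP group lay in batch B and the whole Ctrl group in batch A, so each value of this comparison moves with the liver and pancreatic traces. Values of this comparison with batch as a term rest on DSS 2, the 1 DSS library of batch A.

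Xenobiotic metabolism genes had 10 falls of 29 and 0 rises (0 up and 15 down when adjusted over the list alone; median -0.54). Abcb1a (-1.31 ± 0.19), Cyp2c55 (-1.72 ± 0.27) and Ces1f (-1.23 ± 0.20) were among the falls. The list kept its call with an estimated correlation (adjusted p = 0.0339), and with batch as a term its median was -0.34. Fat oxidation genes had 9 falls of 27 and 0 rises (0 up and 21 down when adjusted over the list alone; median -0.53). Examples were Acaa1b (-2.37 ± 0.45) and Ehhadh (-0.73 ± 0.10). Its adjusted p was 0.0673 with an estimated correlation, and its median with batch as a term was -0.55. Antimicrobial genes had 4 rises and 1 fall of 20 (8 up and 1 down when adjusted over the list alone; median 0.93, adjusted p = 0.224 with an estimated correlation). Il18 (2.55 ± 0.33), the acute-phase protein Saa1 (2.15 ± 0.41), Slpi (3.39 ± 0.69, or 2.05 without ImP 1) and the phospholipase Pla2g2a (1.66 ± 0.38) rose, Defb37 fell (-2.45 ± 0.54). The median with batch as a term was 1.04, and in limma on log2 FPKM it was 0.54. Absorptive genes moved both ways, 5 up and 5 down of 26 (9 up and 9 down when adjusted over the list alone). They did not pass as a list (median 0.06, camera adjusted p 0.397). Aqp4 (2.76 ± 0.35), the chloride/bicarbonate exchanger Slc26a3 (1.85 ± 0.26), Atp12a, the colonic proton/potassium pump (5.45 ± 1.1), Aqp8 (2.33 ± 0.45) and Scnn1a (0.85 ± 0.16) rose. Guca2a, which encodes guanylin (-0.91 ± 0.17), Car1 (-1.61 ± 0.31), Tmigd1 (-1.37 ± 0.28) and Cyp2c55 were among the falls. Interferon-response genes had 0 of 26 members past the threshold in edgeR over all genes and did not pass as a list (median -0.10, camera adjusted p 0.718). The globin gene Hba-a2 (-1.84 ± 0.37) and Alas2, the erythroid enzyme of heme synthesis (-3.05 ± 0.61), fell. They were 2 of 7 erythroid markers (0 up and 5 down when adjusted over the list alone; median -1.41), and that list had an adjusted p of 0.321 with an estimated correlation and a median of -0.52 with batch as a term. Among the 17 lists that camera called here were also smooth muscle markers (median 0.70, or 0.95 with batch as a term), B and plasma cell markers (1.48, or 1.87) and enteric neuron and glia markers (0.38, or 1.57). Their adjusted p was 0.321, 0.57 and 0.636 with an estimated correlation, and in edgeR 0 of their members passed over all genes (15 of 16, 6 of 20 and 0 of 17 up when adjusted over the list alone). The B and plasma cell median was 0.39 without ImP 4 and 0.58 in limma on log2 FPKM, and the enteric median was 0.74 without Ctrl 1, with its call lost without Ctrl 5. Camera further called cytokines and chemokines (0.44), neutrophil markers (0.48), matrix (0.35) and T and NK cell markers (-0.31). With batch as a term their medians were 0.56, 1.15, -0.20 and -0.23. None of these held with an estimated correlation. The neutrophil call was lost without Ctrl 1, Ctrl 5, DSS_ImP 2 or ImP 1, the cytokine call without Ctrl 4 or ImP 1, and the T and NK call without ImP 3. Pla2g2a, Aqp8, Scnn1a, Car1 and Tmigd1 were chosen after their values were seen. Leaving out 1 library ended the call in edgeR, with the highest adjusted p and the libraries in brackets, for Cyp2c55 (0.0533, Ctrl 1 or 4), Ces1f (0.0639, Ctrl 1 or 4), Acaa1b (0.0856, Ctrl 1, 4 or 5 or ImP 3 or 4) and Saa1 (0.101, Ctrl 1, 4 or 5 or ImP 1). Slpi (0.127, Ctrl 1, 4 or 5 or DSS 5 or ImP 1), Defb37 (0.137, Ctrl 1, 4 or 5 or DSS 5 or ImP 1, 3 or 4), Slc26a3 (0.0515, Ctrl 1 or 4) and Atp12a (0.112, Ctrl 1 or 4 or ImP 1) did so too in edgeR. Guca2a (0.0917, Ctrl 1 or 4 or ImP 1), Hba-a2 (0.109, Ctrl 1, 4 or 5 or ImP 1, 3 or 4) and Alas2 (0.102, Ctrl 1, 4 or 5 or ImP 1 or 4) did so too in edgeR.

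In all, 236 genes rose and 207 fell in ImP against Ctrl, 443 in total, and 53.3% of these calls were rises, against 39.4% in limma on log2 FPKM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00632 for Pla2g4f, 0.00564 for Aqp4, 0.0258 for Atp12a, 0.0143 for Ly6g, 0.0278 for Clca4b, 0.00632 for Sis and 0.00866 for Cyp4b1. Large rises were in Atp12a (from 6.76 ± 6.13 to 297 ± 267 CPM), Ly6g (from 3.47 ± 3.77 to 125 ± 100.4 CPM) and Clca4b (from 21 ± 5.28 to 908 ± 1157 CPM, or a log2 change of 5.44 that was 3.58 without ImP 1). Others were in Lrg1 (log2 change 4.19 ± 0.89) and Vsig1 (4.12 ± 0.61). Khdc1a stood at 3.23 ± 4.26 against 0.0416 ± 0.0721 CPM and Sprr2h at 1.1 ± 0.660 against 0.0364 ± 0.0630 CPM. With 0 counts in Ctrl, Krtap13 was at least 17.8-fold and Defb45 at least 14.2-fold higher. The large falls included the liver-expressed genes Ahsg (0.0149 ± 0.0258 against 3.17 ± 0.210 CPM), Apoa2 (log2 change -5.82 ± 1.27), Cyp3a25 (-3.79 ± 0.66), Itih3 (-2.61 ± 0.59) and Ambp (-2.52 ± 0.52), beside Spp1 (-2.94 ± 0.61), H2-Bl (-2.63 ± 0.58) and Defb37 (-2.45 ± 0.54). With batch as a term, estimated from the DSS libraries of batches A and B, 1 gene passed, Gm15884 (log2 change -10.21, edgeR adjusted p 0.0142, chosen after its values were seen). With it 0 of the 443 calls were kept, and 1851 genes had an unadjusted p under 0.05. The log2 change with that term adds the change of DSS 2 against Ctrl to that of ImP against DSS within batch B. It therefore rests on DSS 2, the 1 DSS library of batch A. The change with that term was 4.61 ± 0.88 for Pla2g4f (before 4.11 ± 0.55) and 6.21 ± 1.3 for Ly6g (before 5.17 ± 0.86). It was -3.45 ± 0.62 for Sis (before -2.64 ± 0.35) and -3.50 ± 0.60 for Cyp4b1 (before -2.49 ± 0.36). The SE was wider for each. For Cyp4b1 the term gave -3.48 in DSS against Ctrl as well, so for this gene ImP and DSS hardly differed within batch B. For the liver-expressed genes Apoa2, Itih3 and Ambp the change with that term shrank to -0.46 ± 0.55, -0.60 ± 0.73 and -0.86 ± 0.68. For the other liver-expressed genes it shrank too, from -7.50 to -3.38 ± 1.38 for Ahsg and from -3.79 to -1.96 ± 0.89 for Cyp3a25. Ahsg had 3 counts in total in ImP, under the floor set for groups without counts, so the size of its change is uncertain. A fall of these genes apart from the liver trace is therefore not shown. The change with that term also shrank for Vsig1, to 3.10, and for H2-Bl, to -2.25. The count of 443 was 1269 with DESeq2. It was 49 without Ctrl 1, 51 without Ctrl 4, 208 without ImP 3, 212 without ImP 4, 263 without ImP 1, 271 without DSS 5, 279 without Ctrl 5 and 231 without a low-count filter. Among the genes of this paragraph, calls were lost in edgeR when 1 library was left out, with the highest adjusted p and the libraries in brackets, for Atp12a (0.112, Ctrl 1 or 4 or ImP 1), Ly6g (0.0763, Ctrl 1 or 4), Clca4b (0.111, Ctrl 1, 4 or 5) and Lrg1 (0.148, Ctrl 1, 4 or 5 or DSS 3 or 5 or ImP 1 or 3). Vsig1 (0.0548, Ctrl 1 or 4), Khdc1a (0.138, Ctrl 1, 4 or 5 or DSS_ImP 2 or DSS 5 or ImP 1), Sprr2h (0.131, Ctrl 1, 4 or 5 or ImP 1 or 3) and Krtap13 (0.0502, Ctrl 1) did so too in edgeR. Defb45 (0.11, Ctrl 1, 4 or 5 or DSS 5 or ImP 1), Ahsg (0.089, Ctrl 1 or 4 or ImP 1, 3 or 4), Apoa2 (0.135, Ctrl 1, 4 or 5 or DSS_ImP 2 or ImP 1, 3 or 4) and Cyp3a25 (0.0704, Ctrl 1 or 4) did so too in edgeR. Itih3 (0.151, Ctrl 1, 4 or 5 or DSS_ImP 2 or DSS 3 or ImP 1, 3 or 4), Ambp (0.114, Ctrl 1, 4 or 5 or ImP 1, 3 or 4) and Spp1 (0.118, Ctrl 1, 4 or 5 or DSS 5 or ImP 1 or 3) did so too in edgeR. H2-Bl (0.134, Ctrl 1, 4 or 5 or DSS_ImP 2 or DSS 3 or 5 or ImP 1, 3 or 4) and Defb37 (0.137, Ctrl 1, 4 or 5 or DSS 5 or ImP 1, 3 or 4) did so too in edgeR. Within batch B, all 26 interferon-response genes were higher in ImP than in DSS, 5 of them past the threshold, with a median of 1.96. There the neutrophil median was -1.90 and the cytokine median -0.54, and 29 genes passed (20 up, 9 down).

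DSS_ImP was compared with ImP to ask what DSS changed in colon that had received ImP. Csf3 (ENSMUSG00000038067) and Il36g (ENSMUSG00000044103), an epithelial cytokine of the interleukin-1 family, had 0 counts in ImP and were at least 173-fold and 130.1-fold higher in DSS_ImP. Lcn2 (ENSMUSG00000026822) rose from 3.11 ± 1.61 to 156 ± 102 CPM. Ifi44 fell from 66.0 ± 30.2 to 8.89 ± 5.20 CPM, and Mptx1 (ENSMUSG00000026531), a pentraxin gene of the epithelium, fell from 294 ± 231 to 0.676 ± 0.753 CPM.

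Neutrophil, cytokine, matrix and absorptive lists kept their camera call with an estimated correlation. Neutrophil markers had 13 rises of 17 (14 up and 0 down when adjusted over the list alone; median 5.72, adjusted p = 0.026 with an estimated correlation). S100a9 (8.38 ± 0.83) and Clec4d (5.72 ± 0.63) were among them. Cytokines and chemokines had 17 rises of 28 (19 up and 1 down when adjusted over the list alone; median 2.78, adjusted p = 0.0254 with an estimated correlation). Cxcl3 (7.33 ± 0.70), Il11 (5.87 ± 0.57) and Il1b (4.73 ± 0.47) rose. Matrix genes had 24 rises of 25 (24 up and 0 down when adjusted over the list alone; median 1.56, adjusted p = 0.0254 with an estimated correlation). Lox (3.58 ± 0.32), Thbs1 (3.19 ± 0.31) and Mmp10 (5.68 ± 0.62) were among the rises. Absorptive genes had 15 falls of 26 and 0 rises (0 up and 22 down when adjusted over the list alone; median -0.82, adjusted p = 0.0254 with an estimated correlation). Cdhr5 (-0.82 ± 0.10), Cyp2c55 (-1.64 ± 0.26) and Slc9a2 (-0.89 ± 0.15) fell. Interferon-response genes had 24 falls of 26 and 0 rises (0 up and 24 down when adjusted over the list alone; median -1.77). They included Oas3 (-2.74 ± 0.35), Irf7 (-2.07 ± 0.25) and Zbp1 (-1.49 ± 0.17). Their adjusted p was 0.0727 with an estimated correlation. Camera also called T and NK cell markers (median -0.74) and MHC class II genes (-0.64). Both calls were lost without ImP 4, and that of MHC class II genes also without DSS_ImP 4. Further calls were tuft cell (-0.65, or -0.32 in limma on log2 FPKM), macrophage (0.60) and enteric nerve markers (0.81). None of these held with an estimated correlation. Goblet genes had 6 falls of 19 and 0 rises (0 up and 12 down when adjusted over the list alone; median -0.51, adjusted p = 0.0797 with an estimated correlation). Klk1 (-1.43 ± 0.14) and Atoh1 (-0.89 ± 0.19) were among the falls. Endothelial markers had 9 rises of 15 (12 up and 0 down when adjusted over the list alone; median 0.78, adjusted p = 0.18 with an estimated correlation). Vwf (1.18 ± 0.18) and Pecam1 (1.01 ± 0.19) were among the rises. Erythroid markers had 5 rises of 7 (5 up and 0 down when adjusted over the list alone; median 2.19, adjusted p = 0.146 with an estimated correlation). They were Hba-a2 (2.19 ± 0.37), Alas2 (3.64 ± 0.62), Hbb-bs (2.12 ± 0.41), Hbb-bt (2.21 ± 0.43) and Hba-a1 (1.87 ± 0.41, chosen after its values were seen). In limma on log2 FPKM the medians were 2.72 for neutrophil and -0.33 for goblet genes. Over the 5 comparisons camera called 97 list changes, and 7 held with an estimated correlation: these 4, interferon and xenobiotic genes in DSS against Ctrl, and xenobiotic genes in ImP against Ctrl.

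In all, 982 genes rose and 1097 fell in DSS_ImP against ImP, 2079 in total. Rises made up 47.2% of these calls, against 70.8% in limma on log2 FPKM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.000438 for Csf3, 0.00103 for Il36g, 0.000236 for Lcn2, 0.00269 for Ifi44 and 0.00562 for Mptx1. With 0 counts in ImP, Cstdc4 was at least 78.9-fold, Stfa2l1 59.6-fold, Mrgpra2b 55.6-fold, Stfa2 43.0-fold, Mrgpra2a 31.5-fold, Cstdc5 29.2-fold and Stfa3 13.8-fold higher in DSS_ImP. Ngp stood at 45.0 ± 38.9 against 0.0323 ± 0.0559 CPM. The other large falls were in Krtap3-1 (log2 change -3.42 ± 0.67), Il22ra2, the soluble receptor that binds interleukin 22 (-3.24 ± 0.62), Apol9b (-3.15 ± 0.51) and Pla2g4c (-3.05 ± 0.67). The pancreatic genes of the batch B trace, Ctrb1, Prss2 and Try4, were at least 91.6-fold, 23.7-fold and 16.9-fold lower. Reg2, which is not in the list that defines the trace, was at least 22.0-fold lower. In ImP it stood at 1.25 ± 0.283 CPM, near Prss2 (1.35 ± 0.298 CPM), and both had 0 counts in DSS_ImP. A fall of Reg2 apart from the trace is therefore not shown. No batch holds both groups, so no within-batch value exists. The count of 2079 was 3152 with DESeq2, 1153 with only these groups fitted, 997 without DSS_ImP 3, 1356 without ImP 3 and 1376 without DSS_ImP 2. Among the genes of this paragraph, calls were lost in edgeR when 1 library was left out, with the highest adjusted p and the libraries in brackets, for Stfa2 (0.0554, DSS_ImP 3), Cstdc5 (0.0756, DSS_ImP 3), Stfa3 (0.132, DSS_ImP 2 or 3 or ImP 1, 3 or 4) and Pla2g4c (0.0701, DSS_ImP 3). Ctrb1 (0.0935, DSS_ImP 2, 3 or 4 or ImP 1, 3 or 4), Prss2 (0.128, DSS_ImP 2, 3 or 4 or DSS 3 or 5 or ImP 1, 3 or 4), Reg2 (0.0874, DSS_ImP 2, 3 or 4 or ImP 1, 3 or 4) and Try4 (0.0748, DSS_ImP 2 or 3 or ImP 1, 3 or 4) did so too in edgeR.

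**Figure D4:**
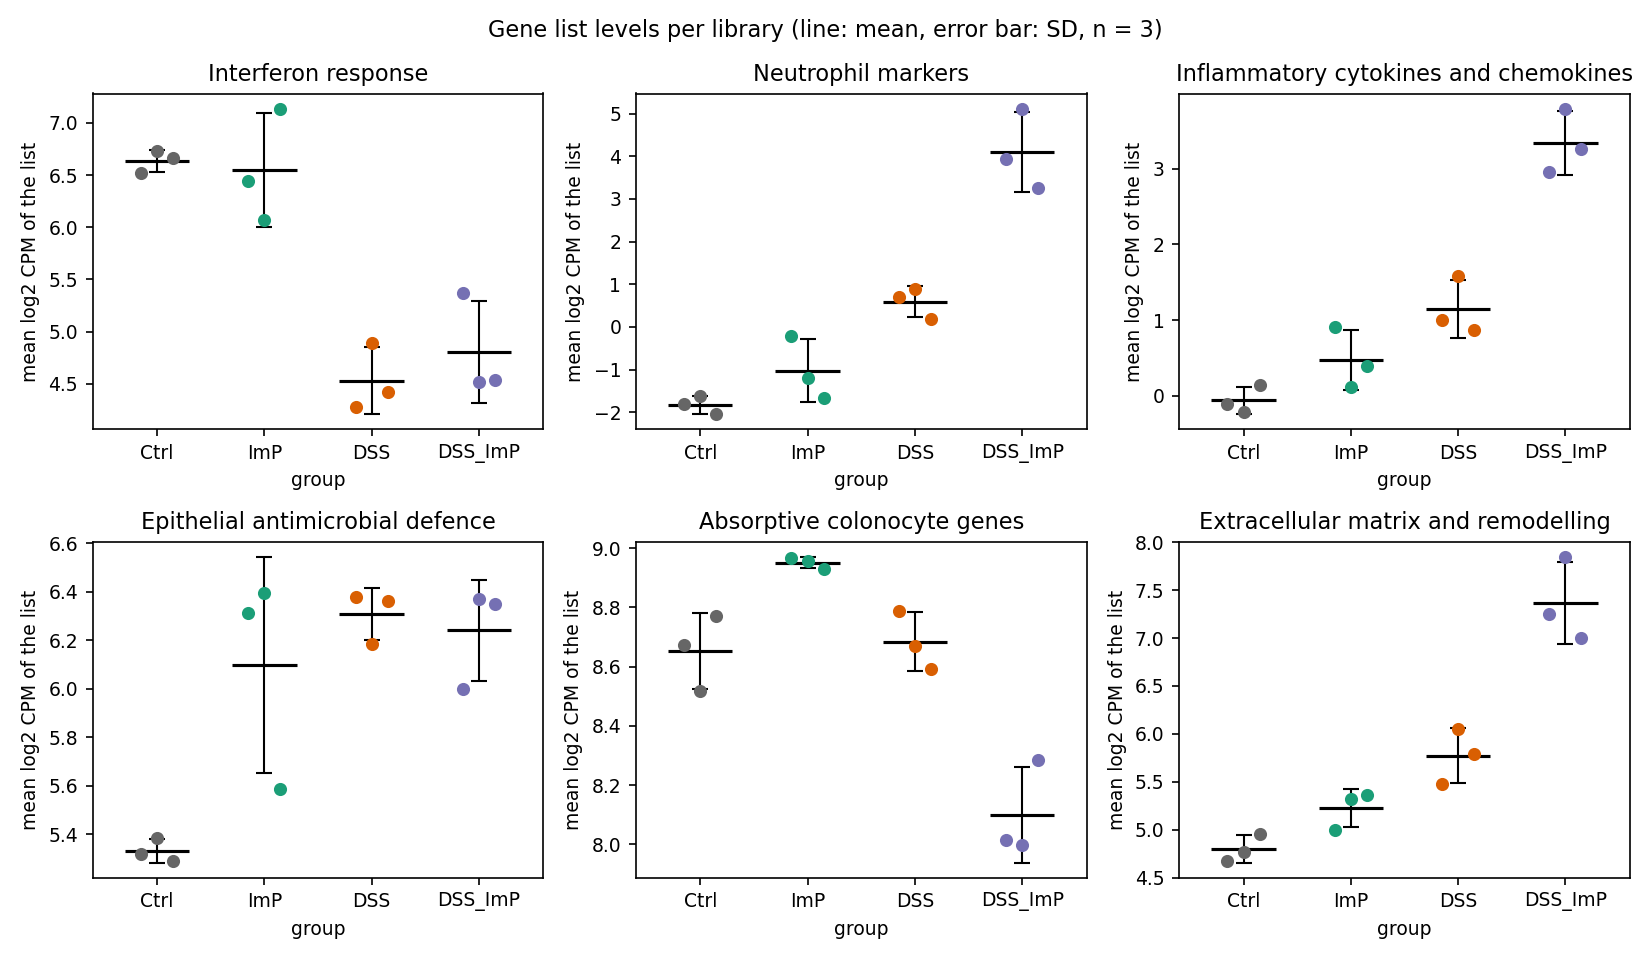
Mean log2 CPM over the members of 6 gene lists in each library, by group, with 1 point per library, a line at the group mean and a bar of 1 SD (n = 3). The interferon list is lower in the DSS and DSS_ImP libraries than in Ctrl and ImP, with median log2 changes of -1.99 in DSS against Ctrl and -1.77 in DSS_ImP against ImP.

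The interaction asks whether DSS changed genes by a different amount with ImP than without it. The difference is the log2 change of DSS with ImP minus that without it. It was 4.06 ± 0.52 for Arg1, an arginase, and 3.67 ± 0.51 for Selp, the selectin of activated endothelium. For Chst11 it was 2.62 ± 0.37, for Pde1a 1.75 ± 0.26 and for Prss23 1.36 ± 0.20. Prss23 had a lower mean CPM in DSS_ImP than in ImP, so its positive difference does not mark a rise there. Arg1 was also called in ImP against Ctrl, a comparison that moves with the liver trace. Whether the liver trace of Ctrl and DSS 2 enters the difference of Arg1 was not tested. For Klf4 the difference was -1.07 ± 0.16, for Sectm1b -0.98 ± 0.12, for Shroom3 -0.98 ± 0.14, for Vipr1 -0.89 ± 0.13 and for the clock gene Per2 -0.72 ± 0.11. None of these genes passed: each had an adjusted p of 0.0506 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 10 passed with the DESeq2 Wald test, limma on log2 FPKM, the stricter filter and counts divided by 4. They also passed without Ctrl 5 and without DSS_ImP 4 (for Arg1, edgeR's adjusted p was 0.0209 and 0.00331), 8 of them passed without ImP 4, and Arg1 passed without DSS 2. edgeR called 0 genes, with 2631 at an unadjusted p under 0.05, while DESeq2 called 706 and limma on log2 FPKM 72. Without DSS_ImP 4 edgeR called 476 genes, without Ctrl 5 48, without ImP 4 30, without DSS 2 8, without Ctrl 1 1 (Selp) and without DSS 3 1 (Cwh43, chosen after its values were seen). Camera called 15 lists, of which 0 held with an estimated correlation. The median difference was 2.26 for neutrophil markers, 1.71 for cytokines and chemokines, 0.97 for matrix and -0.51 for absorptive genes. Their adjusted p was 0.181, 0.121, 0.124 and 0.0975 with an estimated correlation, and 0 of their members passed in edgeR over all genes.

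The effects of DSS with and without ImP were compared across genes, which are not independent replicates. Over 22279 genes the log2 changes of DSS against Ctrl and of DSS_ImP against ImP, which share no library, had a Pearson correlation of 0.282 and a Spearman correlation of 0.299, with a slope of 0.312. Over genes above the median expression the Pearson correlation was 0.597. With 1 library left out it was 0.166 (no DSS 2) to 0.253 (no DSS_ImP 2), but those fits covered more genes, 23014 to 23145. The comparisons shared 75 rises and 242 falls, where 11.9 and 17.4 would be shared by independent draws, and 1 gene, Vipr1, a receptor for vasoactive intestinal peptide, rose in the first (0.40 ± 0.09) and fell in the second (-0.49 ± 0.09). Of the 623 genes called in DSS against Ctrl, 31.1% had the opposite sign in DSS_ImP against DSS. The SE of that share was 15.5 (jackknife). Simulated groups with DSS_ImP drawn from the DSS means, where only the shared DSS libraries link the comparisons, gave 66.9% ± 1.36 (SD over 20 draws) among their own 1425 to 1687 called genes per draw, and so over other genes than the 623. Of those 623 genes, 9 were called in the opposite direction in DSS_ImP against DSS and 145 in the same direction, 48 up and 97 down. The opposite and same counts were 2 and 48 without DSS 5, 29 and 64 without DSS 3, and 40 and 211 without DSS_ImP 4. DSS against Ctrl and ImP against Ctrl shared 113 rises and 102 falls and 0 genes in opposite directions. Both comparisons use the same 3 Ctrl libraries, all of batch A. Their Pearson correlation was 0.566, against 0.502 ± 0.0143 (SD over 20 draws) in simulations that share only those libraries, and their covariance 0.554 against 0.184.

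Hox genes, which mark position along the gut, differed between the groups as well. Hoxa13 (ENSMUSG00000038203) stood at 4.39 ± 3.65 CPM in Ctrl, 36.1 ± 7.56 in ImP, 28.3 ± 3.92 in DSS and 35.4 ± 3.48 in DSS_ImP. It rose in DSS against Ctrl (log2 change 2.68 ± 0.43) and in ImP against Ctrl (3.04 ± 0.43). Hoxa9, Hoxa10 and Hoxa11, chosen after their values were seen, also rose in both, by 2.06 ± 0.41, 1.91 ± 0.32 and 1.76 ± 0.26 in DSS and by 2.20 ± 0.42, 1.92 ± 0.32 and 1.51 ± 0.26 in ImP. Within batch A their changes in DSS were 2.12, 1.98 and 2.10, and that of Hoxa13 was 2.85, from 1 DSS library. Hoxa5 and Hoxa7 rose in both comparisons too, by 1.16 ± 0.25 and 1.11 ± 0.27 in DSS. In ImP they rose by 1.70 ± 0.26 and 1.20 ± 0.27, and Hoxa3 and Hoxa6 rose in ImP alone. Hoxb6, also chosen after its values were seen, stood at 78.6 ± 7.85 CPM in Ctrl, 44.9 ± 8.94 in DSS, 35.4 ± 12.1 in ImP and 11.1 ± 5.33 in DSS_ImP, and it fell in DSS_ImP against DSS (-2.01 ± 0.32). Hoxb3, Hoxb4, Hoxb5, Hoxb7, Hoxb8, Hoxb9, Hoxd3, Hoxd4 and Hoxd8 fell in DSS_ImP against DSS too, while Hoxd13 rose. Hoxb13 ranged from 0.509 to 17.0 CPM in Ctrl, 8.11 to 21.2 in DSS, 32.7 to 126 in ImP and 25.3 to 112 in DSS_ImP, and passed in none of the 4 comparisons. These differences move with every gene group above that separates Ctrl from the other groups or DSS_ImP from DSS.

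**Figure D5:**
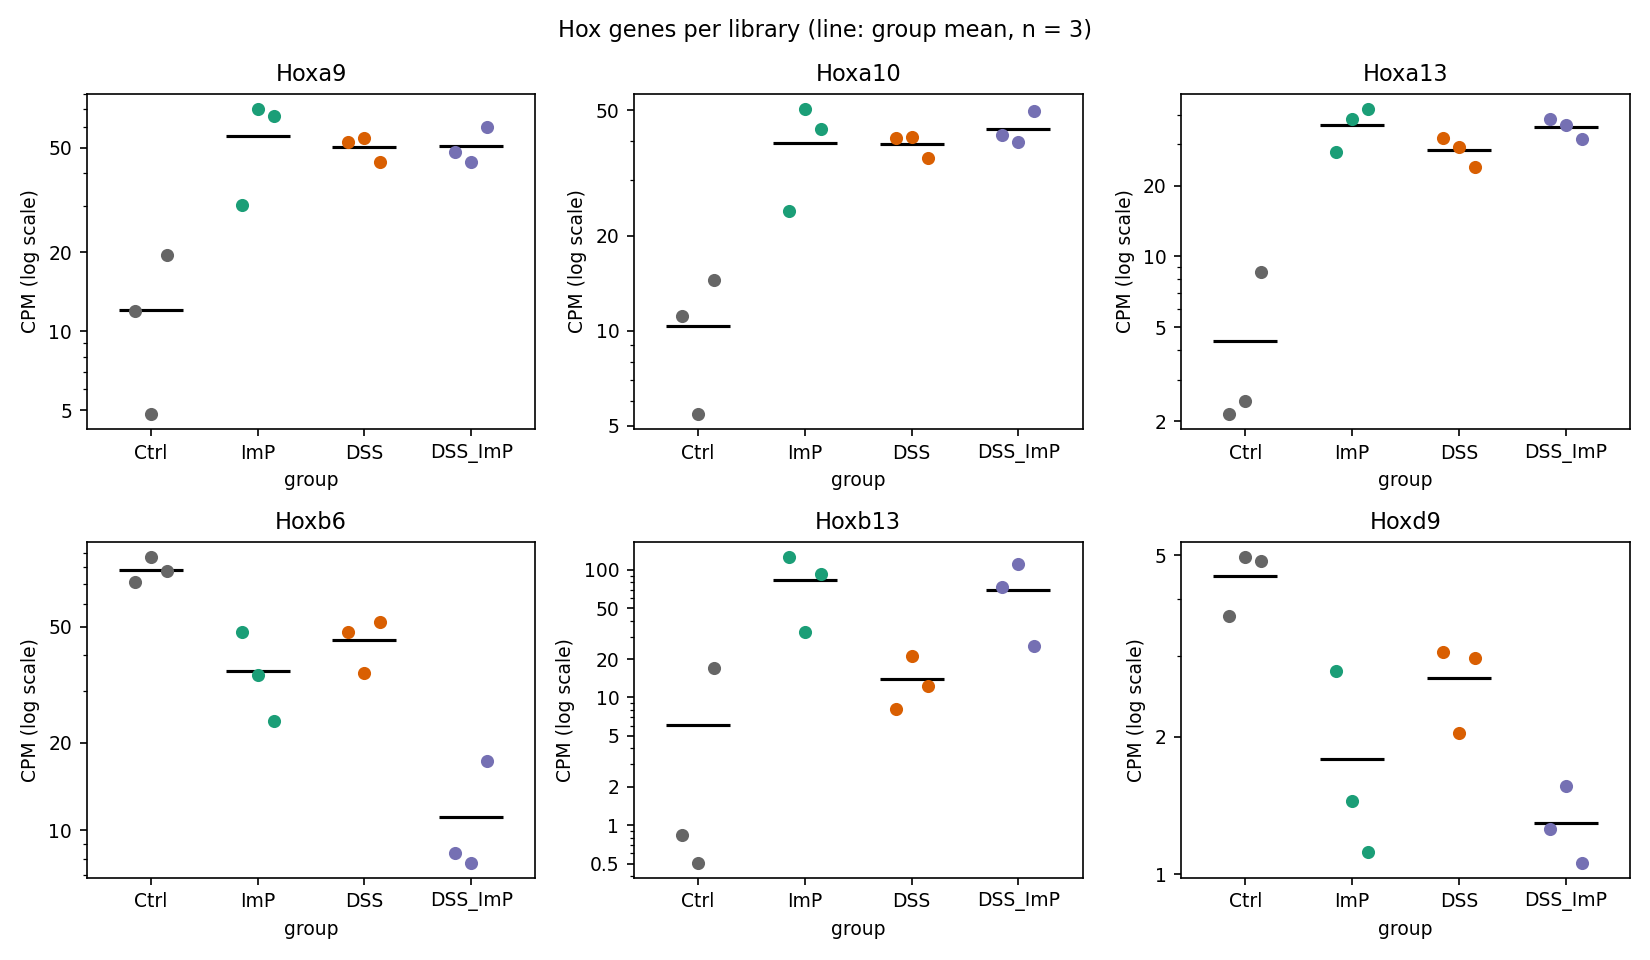
CPM on a log axis of Hoxa9, Hoxa10, Hoxa13, Hoxb6, Hoxb13 and Hoxd9 in the 12 libraries, with 1 point per library and a line at each group mean. Hoxa13 averages 4.39 ± 3.65 CPM in Ctrl and at least 28.3 CPM in each other group, and Hoxb6 averages 78.6 CPM in Ctrl and 11.1 CPM in DSS_ImP.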

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

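The tests of explanations and the counts over other splits in this part were all chosen after the results were seen. The list comparisons themselves were planned. Bootstrap intervals in this part resample the genes of a list and not the libraries, so they do not measure the spread between libraries.

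Gene lists are given here because camera found that the DSS change with ImP differed from that without it. The median difference (DSS_ImP minus ImP, less DSS minus Ctrl, on the log2 scale) was 1.71 for inflammatory cytokines and chemokines, 2.26 for neutrophil markers, 0.55 for monocyte and macrophage markers, 0.97 for extracellular matrix, 0.61 for endothelial markers, 1.45 for erythroid markers and 0.51 for cell cycle genes. It was -1.08 for epithelial antimicrobial defence, -0.49 for goblet cell and mucus genes, -0.51 for absorptive colonocyte genes, -0.41 for junction genes, -0.41 for smooth muscle markers and -0.24 for circadian clock genes. For pancreatic acinar markers it was -9.94, a list that holds the pancreatic trace of batch B, and for histidine and histamine handling 0.37. Members of the pancreatic list such as Ctrb1 and Prss2 had 0 counts in DSS_ImP, so the size of that median is not measured, and in limma on log2 FPKM it was -1.19, with -0.25 for junction and -0.13 for circadian clock genes there. With an estimated correlation the adjusted p of these 15 lists ranged from 0.0975 to 0.662, so 0 held there, and fry called 5. Cell cycle genes had 0.33 without DSS_ImP 2, 0.23 without DSS 2 and 0.90 without DSS 3, and smooth muscle markers -0.17 without ImP 3. The histidine call was lost without Ctrl 4 (0.46), DSS_ImP 2 (0.31), DSS 3 (0.40), DSS 5 (0.27) or ImP 4 (0.40). It was kept at 0.96 without DSS 2 and 0.24 without ImP 3. In that list 3 members (Uroc1, Ftcd and Amdhd1) move with the liver trace. Since DSS_ImP forms batch C alone, a batch difference and an interaction cannot be told apart for any of these lists.

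Of the other splits of the libraries, 3 against 3 gives 10 splits, too few for a share under 0.05. DSS against Ctrl called 623 genes and the highest other split 0, DSS_ImP against DSS 1789 and 1, ImP against Ctrl 443 and 1, and DSS_ImP against ImP 2079 and 1, so that 1 split, the real one, reached each count. For the interaction, 8 of 100 drawn splits gave at least the 2631 genes found at an unadjusted p under 0.05. Each of the others that did so kept ImP apart from Ctrl or DSS_ImP apart from DSS and carries that difference, so this count neither excludes chance nor speaks for it. The highest other split gave 4371 genes. It set Ctrl 1, Ctrl 5 and ImP 3 against Ctrl 4, ImP 1 and ImP 4 and kept DSS_ImP apart from DSS, so it carries the difference of 1789 genes.

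Hoxa9 to Hoxa13 were lower in Ctrl than in the other groups. Hoxa5 and Hoxa7 were lower in Ctrl than in DSS and ImP too, so the pattern was not confined to Hoxa9 to Hoxa13. A larger share of non-epithelial cells outside Ctrl stays open. In DSS against Ctrl the median of Hoxa9 to Hoxa13 exceeded that of 48 markers of muscle, nerve and endothelium by 1.67 (1.98 against 0.31). The 95% bootstrap interval of the difference, over genes, was 1.45 to 2.39. But Hoxa9, Hoxa10 and Hoxa11 were chosen after their values were seen, so an excess was in part built in. The markers also leave out the matrix list, which had a median of 0.64. The library batch of the Ctrl samples cannot be told apart from the group, because only 1 DSS library lies in that batch; in it Hoxa9, Hoxa10, Hoxa11 and Hoxa13 were above every Ctrl library. More proximal sampling of the colon in Ctrl stays open too, since over 35 Hox genes the correlation of paralog number with the ImP against Ctrl change was 0.216 (Spearman, two-sided permutation p 0.211) and with the DSS against Ctrl change -0.0450 (permutation p 0.797). An effect of DSS and of ImP on these genes, the explanation that the design names, also stays open and was not tested apart from these.

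Neutrophil markers were higher in DSS_ImP than in DSS. A single DSS_ImP or DSS library is argued against, since the lowest median over the 12 fits with 1 library left out was 3.08, and so is a lower epithelial share as the whole cause, since neutrophil markers exceeded T and NK cell markers by 4.07 (3.56 against -0.51; 95% bootstrap interval 2.99 to 5.07). By library, the mean log2 CPM of neutrophil markers was 3.25 to 5.12 in DSS_ImP and 0.18 to 0.90 in DSS. That of T and NK cell markers was 2.04 to 2.23 in DSS_ImP and 2.41 to 2.52 in DSS. Endothelial (0.71) and enteric nerve (0.75) medians were above 0 too, so a lower epithelial share as a part of the cause stays open. The library batch of the DSS_ImP samples cannot be told apart from the group, because 0 batches hold both. Sampling position along the colon was not tested for this pattern and stays open. Hoxb6 averaged 11.1 CPM in DSS_ImP and 44.9 CPM in DSS, and Hoxd13 14.1 and 0.258 CPM, and both were called. Hoxb3, Hoxb4, Hoxb5, Hoxb7, Hoxb8, Hoxb9, Hoxd3, Hoxd4 and Hoxd8 fell as well. Their log2 changes ran from -0.75 (Hoxb9) to -1.57 (Hoxb8). Hoxa13 (35.4 and 28.3 CPM) was not called, and neither was any other Hoxa gene. An effect of ImP during colitis is therefore a hypothesis beside these.

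Interferon-response genes were lower in DSS than in Ctrl. A library batch as the whole cause is argued against, because within batch B these genes were 1.96 higher in ImP than in DSS (95% bootstrap interval over genes 1.57 to 2.18). The mean log2 CPM of the list was 6.07 to 7.14 in the ImP libraries, and 4.89 and 4.42 in DSS 3 and DSS 5. Fewer immune cells are argued against as the whole cause, because the list fell by 1.49 more than T and NK cell markers (difference -1.49, interval -2.0 to -1.05). MHC class II genes had a median of -0.80, so a part of it stays open. Sampling position along the colon stays open. ImP against Ctrl, with a like Hoxa change, exceeded DSS against Ctrl by 2.09 over the list (interval 1.64 to 2.32; ImP median -0.10). But Hoxb13 stood at 32.7 to 126 CPM in ImP and 8.11 to 21.2 CPM in DSS, so these groups were not alike in Hox genes. An effect of DSS on the interferon response is a hypothesis beside it. A change within the immune or epithelial cells was not tested.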

How the results depend on the processing

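Counts divided by 4, batch as a term, and list tests with 1 library left out were chosen after seeing the data, and the other alternatives were planned. For changed counts the cause was not tested, except that leaving out libraries or groups leaves fewer samples. The number of genes called, in the order DSS with Ctrl, DSS_ImP with DSS, ImP with Ctrl, DSS_ImP with ImP and interaction, was 623, 1789, 443, 2079 and 0. With the DESeq2 Wald test it was 1457, 3188, 1269, 3152 and 706. With only the groups compared it was 877, 721, 516 and 1153, without a low-count filter 446, 1253, 231, 1628 and 0, and with batch as a term 52 for DSS with Ctrl and 1 for ImP with Ctrl. For the interaction, limma on FPKM called 72, the stricter filter 46 and counts divided by 4 18. DESeq2 size factors stayed within 1.5 times each count, as did limma on FPKM, the stricter filter and counts divided by 4 for the 4 pairwise comparisons. With 1 library left out the counts ranged from 268 (no Ctrl 4) to 779 (no DSS_ImP 3), from 491 (no DSS_ImP 3) to 2616 (no DSS_ImP 4), from 49 (no Ctrl 1) to 527 (no DSS_ImP 3), from 997 (no DSS_ImP 3) to 2490 (no DSS_ImP 4) and from 0 (no Ctrl 4, among others) to 476 (no DSS_ImP 4).

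With the replicate number of the labels as a block (replicate block), the counts were 10, 351, 0, 688 and 2, the last being Arg1 (4.34, edgeR adjusted p 0.0289) and Hp (4.21, adjusted p 0.0289; chosen after its values were seen). The numbers do not appear to pair the libraries: over 9 pairs with the same number, correlations of what the groups leave ran from -0.11 to 0.083, and 2 of 12 libraries correlated best with their own number.

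Camera called 19, 22, 17, 24 and 15 lists in the same order. With an estimated correlation 2, 0, 1, 4 and 0 were called, with fry 7, 12, 2, 17 and 5. Of 97 list calls, 91 kept direction and call with the block and 91 to 95 with 1 library left out. Of 36 with batch as a term, 24 did, 8 lost the call and 4 reversed in camera's direction: pancreatic acinar markers at -4.01 in DSS with Ctrl and -3.94 in ImP with Ctrl, matrix at -0.20 and histidine and histamine handling at 0.085 in ImP with Ctrl. Pancreatic markers hold the trace that defines batch B. Immediate early genes in DSS with Ctrl, among the 8, had a median of 0.15 and then of -0.0064. Cell cycle genes in DSS with Ctrl ranged from -0.51 (no DSS 3) to 0.20 (no DSS 2), a reversal in camera's direction. Other calls were lost with a median that changed sign: enteric neuron and glia markers in DSS with Ctrl at -0.066 (no DSS 2), adipocyte markers in DSS_ImP with DSS at 0.14 (no DSS 5) and cholesterol synthesis in ImP with Ctrl at 0.025 (no ImP 4). With the replicate block this held for cell cycle genes in DSS with Ctrl (0.093) and adipocyte markers in DSS_ImP with DSS (0.43). Of the 333 values of named genes, 10 belong to the interaction and were not called in the main fit. A value is said to keep its call if it was called, or not called, as in the main fit. Of the 333, 0 reversed. With 1 library left out 254 to 304 kept their call, with DESeq2 size factors 333, with DESeq2 314 and without a filter 281. With the replicate block 131 kept it and 201 lost it, and with batch as a term 17 of 111 kept it and 94 lost it.

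The correlation of DSS effects with and without ImP, 0.282 over all genes, was 0.741 over genes called in DSS with Ctrl and 0.597 over genes above the median expression. With 1 library left out it was 0.166 (no DSS 2) to 0.253 (no DSS_ImP 2), over larger sets of 23014 to 23145 genes. The share of opposite signs, 31.1%, was 36.4% among 313 genes with an absolute log2 change of at least 1, and 25.3% (no DSS 5) to 43.5% (no DSS 3) with 1 library left out. A pseudocount of 0.1 was not run, because FPKM was not the unit of the main test, and batch as a term could not be fitted for DSS_ImP or the interaction. Depth leaves genes with 0 counts in a group with a bound on their change. Whether depth or spread between replicates limits more was not tested. With 3 libraries per group, 56.6% to 69.8% of simulated 4-fold changes were recovered in the pairwise comparisons.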
